A study of Homo sapiens with 6 samples.

How the data were processed

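RNA sequencing of 6 H69 samples was analysed from 1 deposited table of 64253 genes. Samples were grouped by the treatment given in the labels, with 3 vehicle and 3 TGF-beta libraries. Per the submitters' processing notes, the tools used were bcl2fastq, STAR 2.6.1 and featureCounts of the Subread package, with genome build hg38. The count columns hold whole-number reads per gene, not normalized, per the file headers and the values the authors deposited. The RPKM columns, per the file headers, hold RPKM by the authors, counts scaled to gene length and library size. From the values, they equal the count divided by gene length plus 1 and by a library total of which the counts in the table make up 42.0 ± 0.126% in vehicle and 43.2 ± 0.0623% in TGF-beta libraries (mean ± SD, n = 3). What that larger total counts is not given in the sources used here, nor are the strand setting, the handling of multi-mapped reads or the annotation release. Reads of overlapping, antisense or near-identical genes therefore may be split between them. Of the 67 named genes, 14 overlap another tested gene: ADAM19, ANGPTL4, FAP, JUNB, OVOL1, XAF1, KRT7, XBP1, HSPG2, S100A4, IFIT2, TCF21, SDPR and SNTB1. Overlaps with untested genes, or with genes of much lower mean CPM than the named gene, were not counted. Current names were matched for 20343 of the genes tested (96.9%).

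Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling (factors of 1.04 ± 0.00576 in vehicle and 0.957 ± 0.00503 in TGF-beta libraries), filterByExpr with its minimum count of 10, and the robust quasi-likelihood test of TGF-beta against vehicle, which gave a common biological coefficient of variation of 7.88%. Benjamini-Hochberg adjustment covered the 20992 genes passing the filter, and a gene was called at an adjusted p under 0.05. Log2 fold changes come from the fitted model. Their standard error is the log2 fold change divided by the square root of the F statistic. CPM values use the TMM scaling, and the mean ± SD is over the 3 libraries of a condition. The total count per library ranged from 37205862 to 54160521, and after TMM scaling 1 CPM corresponds to 35.7 to 56.2 reads. Fold changes of genes with very few counts depend on the model's prior count.

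The 23 gene lists, holding 561 genes of which 512 were tested, were fixed from general knowledge before the data were examined, as were the designs and the 11 alternatives. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01, adjusted over the 23 lists. Of these, 10 were called higher and 1 lower, and 0 with an estimated correlation (lowest adjusted p = 0.0563; 9 lists at an unadjusted p under 0.05). The named genes were chosen by a rule fixed at the same time: the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between conditions; for each list the called members with the largest rise and fall; the 3 smallest p-values; and a fixed set that includes SMAD7, FN1, CDH1, KRT7, KRT19 and EP300. Other list members given as examples were chosen after their values were seen. Of the 67 genes the rule selects, 65 were called; some results are not reported here.

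The steps were tested on simulated data with 10 sets of counts drawn from the means and sizes of these libraries for the 20992 genes tested. Of genes changed 1.2-fold, 1.5-fold, 2-fold and 4-fold, 13.4%, 76.4%, 95.4% and 98.4% were recovered. Of 1580 calls, 162 were of unchanged genes, which is 10.3% and above the nominal share of 0.05. Each fold was given to 500 genes over the 10 sets together, far fewer per set than the 40.1% of genes called in the data. These shares therefore need not carry over to the data. None of 20 unchanged lists was called in the last set. Its genes were drawn independently, so this does not cover lists whose genes vary together. Library measures were compared by exact permutation tests, which cannot give p below 0.1 for 3 against 3.

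The labels number the replicates 1 to 3 in both conditions, and the fit of all 6 libraries used no block. Alternatives were RLE size factors, library totals alone, no filter, a filter of at least 1 CPM in 3 samples, DESeq2 1.42.0, limma on log2(RPKM + 1) and log2(RPKM + 0.1) for genes with a mean RPKM of at least 0.5, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. The log2 scale of RPKM was computed from the deposited values, and was used for those alternatives alone. Genes on the Y chromosome and XIST were not named. Splicing, sequence variants and reads outside the table were not analysed here.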

Results

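Gene expression was measured by RNA sequencing in H69 cells, an immortalised line of human cholangiocytes, the epithelial cells that line the bile ducts. Cells at passages 30 to 32 received vehicle or recombinant human TGF-beta at 10 ng/ml for 16 h, and each condition had 3 libraries. TGF-beta is a cytokine that signals through SMAD transcription factors and is known for driving matrix production in fibrosis. The series asked which genes change expression when a cholangiocyte line meets this cytokine. The deposited counts per library summed to 39971568, 54160521 and 49604277 for vehicle replicates 1, 2 and 3, and to 37205862, 47314515 and 40765451 for TGF-beta replicates 1, 2 and 3. The labels do not state that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

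The condition was the largest source of variation among the libraries. The first principal component of log2 CPM (counts scaled to library size) held 74.4% of the variance and separated the conditions. Pearson correlations across genes were 0.991 to 0.997 within a condition and 0.973 to 0.976 between conditions. The second component held 11.6% and set vehicle replicate 1 (36.6) apart from vehicle replicates 2 (-14.9) and 3 (-18.7). Each library pair within a condition differed by more than sampling noise, with a chi-square per degree of freedom of at least 2.5, so no library was counted as a duplicate. The 20 most abundant genes took 6.27 ± 0.359% of counts in vehicle and 8.03 ± 0.193% in TGF-beta libraries (mean ± SD, n = 3 each), ribosomal protein genes took 3.90 ± 0.154% and 3.34 ± 0.0292%, and mitochondrial genes took 3.31 ± 0.246% and 3.69 ± 0.160%. An exact two-sided permutation test gave p = 0.1 for each of these shares, the smallest value that 3 against 3 libraries allow.

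**Figure D1:**
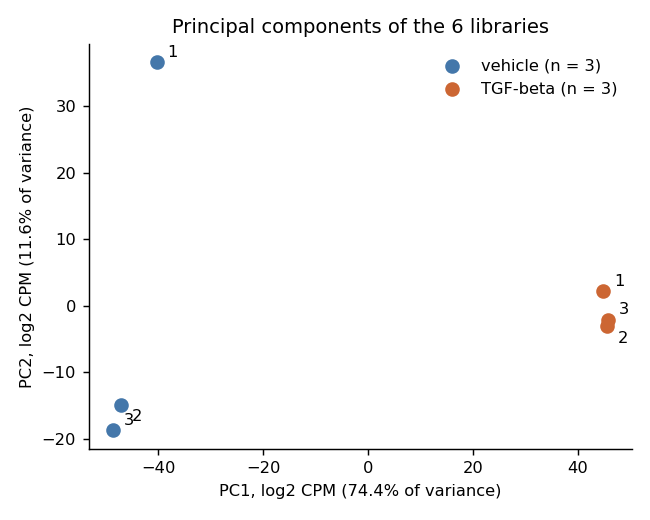
Principal components of log2 CPM over the tested genes, with 1 point per library and the replicate number beside it. PC1 (74.4% of variance) separates TGF-beta from vehicle, and PC2 (11.6%) separates vehicle replicate 1, at 36.6, from the other vehicle libraries.

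TGF-beta raised genes of SMAD feedback, collagens and other matrix components, matrix-modifying enzymes and the contractile cytoskeleton, and lowered 18 of 32 proliferation genes, 17 of them by at most 0.52 on the log2 scale and E2F2 by 1.07. These list calls come from camera with a preset correlation, and with an estimated correlation none was called (lowest adjusted p = 0.0563; 9 lists at an unadjusted p under 0.05). FN1, which encodes fibronectin, rose from 683 ± 49.7 to 2646 ± 56.0 CPM (mean ± SD, n = 3), a log2 fold change of 1.95 with a standard error (SE) of 0.06. INHBB, the inhibin beta B subunit, fell from 25.1 ± 2.06 to 1.87 ± 0.0735 CPM, a log2 fold change of -3.75 (SE 0.09). KRT7 and KRT19, keratins used as bile duct markers, parted: KRT7 rose from 1538 ± 169 to 2966 ± 153 CPM, while KRT19 measured 326 ± 94.6 and 289 ± 20.8 CPM and was not called.

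Of 20992 genes tested, 4145 were higher and 4278 lower with TGF-beta at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 40.1% of those tested. At least 2-fold changes were found for 1004 of the higher and 753 of the lower genes. The CPM values of the conditions did not overlap for 52.3% of the genes, where chance gives 10% for 3 against 3. Scaling by library totals alone shifted the median log2 fold change to -0.14 and the split to 2698 higher and 7282 lower, so that 27.0% of called genes were higher rather than 49.2%; directions below are relative to the TMM scaling. In simulated counts from these libraries, 10.3% of calls were false, above the nominal share, and 13.4% of genes changed 1.2-fold were recovered against 95.4% of those changed 2-fold. Far fewer genes were changed in the simulation than the 40.1% called here, so these shares need not carry over.

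**Figure D2:**
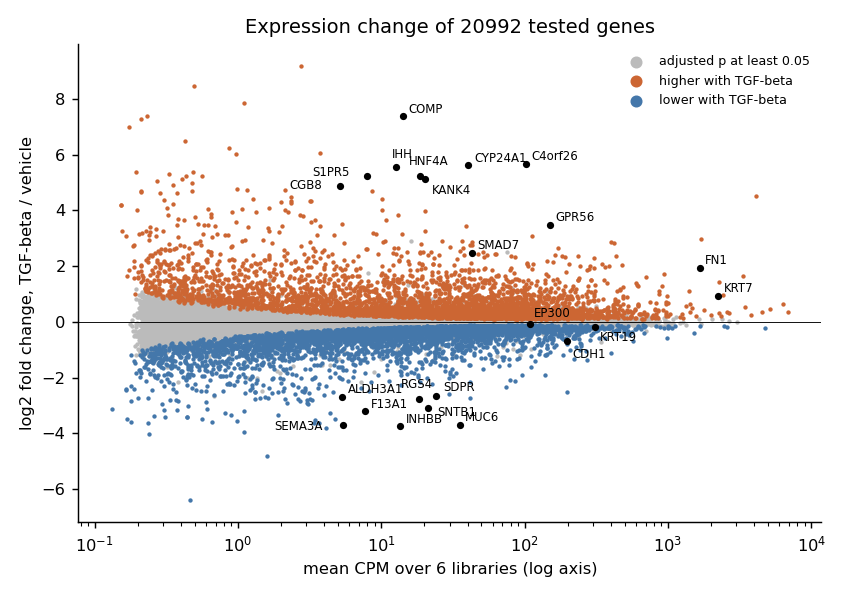
Log2 fold change (TGF-beta over vehicle) against mean CPM on a log axis for the 20992 tested genes, coloured by the edgeR call at an adjusted p of 0.05, with some of the genes of largest change, smallest p or fixed interest named in black. The 4145 higher genes lie above and the 4278 lower genes below 0, with COMP at 7.38 and INHBB at -3.75.

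The 8 largest rises among protein-coding genes with a mean of at least 5 CPM started from means of at most 3.89 CPM in vehicle. COMP, a cartilage matrix glycoprotein (ENSG00000105664, hg38 chromosome 19, 18782773 to 18791314), rose from 0.171 ± 0.0570 to 28.2 ± 1.90 CPM, a log2 fold change of 7.38 (SE 0.14). C4orf26, now named ODAPH and known from tooth enamel, rose from 3.89 ± 0.333 to 199 ± 6.21 CPM and had the smallest p of all genes (adjusted p = 1.71e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CYP24A1, the vitamin D 24-hydroxylase, rose from 1.58 ± 0.516 to 79.6 ± 7.0 CPM. HNF4A, a transcription factor of hepatocytes (ENSG00000101076, chromosome 20, 44355700 to 44432845), rose from 0.956 ± 0.0273 to 36.1 ± 1.5 CPM, a log2 fold change of 5.24 (SE 0.08). The hedgehog ligand IHH (5.57), the sphingosine-1-phosphate receptor gene S1PR5 (5.24), KANK4 (5.13) and the chorionic gonadotropin beta gene CGB8 (4.88) completed the group on the log2 scale. IHH was uneven in vehicle, at 1.41 CPM in replicate 1 against 0.142 and 0.174 CPM, and without vehicle replicate 1 its log2 fold change was 7.27. GPR56, an adhesion receptor gene now named ADGRG1, was among the 3 genes with the smallest p and rose from 24.4 ± 0.984 to 276 ± 15.1 CPM.

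CGB8 lies in a block on chromosome 19 (hg38, 49015980 to 49072941) in which 14 consecutive tested genes rose, from LHB, the luteinizing hormone beta gene, to the potassium channel gene KCNA7. Their log2 fold changes ran from 3.85 for CGB7 to 6.07 for CGB5, and their summed counts from 764 over the vehicle libraries to 11982 over the TGF-beta libraries. KCNA7 rose from 0.632 ± 0.0230 to 16.7 ± 1.26 CPM and the neurotrophin gene NTF4 from 1.18 ± 0.263 to 19.02 ± 1.31 CPM. The LHB and CGB genes are near-identical copies and some members overlap, so the share of counts of each is uncertain. The nearest flanking genes measured -0.15 (RUVBL2) and 0.13 (SNRNP70) on the log2 scale. The block was singled out after its values were seen.

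**Figure D3:**
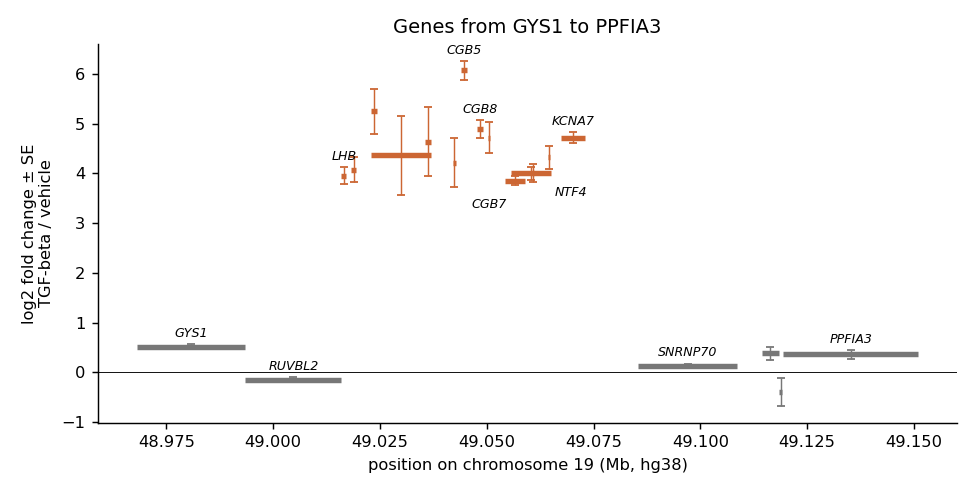
Log2 fold change (TGF-beta over vehicle) with SE of the tested genes from GYS1 to PPFIA3 against their position on chromosome 19 in megabases of hg38, with horizontal bars for the gene spans. The 14 genes of the block (orange) lie between 3.85 and 6.07, and the flanking genes (grey) lie between -0.39 and 0.52.

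The largest falls included genes of secreted and signalling proteins. MUC6, a secreted gel-forming mucin, fell from 65.4 ± 22.2 to 5.11 ± 0.682 CPM, a log2 fold change of -3.69 (SE 0.35). SEMA3A, an axon guidance ligand, fell from 10.0 ± 1.56 to 0.774 ± 0.0900 CPM, and RGS4, a regulator of G protein signalling, from 31.9 ± 11.4 to 4.70 ± 0.247 CPM. SNTB1 (-3.10), ALDH3A1 (-2.68) and SDPR, now named CAVIN2 (-2.65), also fell on the log2 scale, as did F13A1, the coagulation factor XIII A subunit (-3.20). F13A1 measured 5.65 CPM in vehicle replicate 1 against 17.1 and 19.2 CPM in replicates 2 and 3. Without TGF-beta replicate 1, 2 or 3 its adjusted p was 0.0502, 0.0628 and 0.0589 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With vehicle replicate 1 left out, the same edgeR quasi-likelihood test gave F13A1 an adjusted p of 1.39e-21 at a log2 fold change of -3.57. That fit kept only vehicle replicates 2 and 3, which lay close together. Small p-values from fits without vehicle replicate 1, here and below, therefore need not make a call firmer.

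Among SMAD feedback genes and early targets, 15 of 17 tested members rose and none fell, with a median log2 fold change of 2.10. JUNB (3.08), the secreted matrix protein gene TGFBI (2.97), the pathway inhibitor gene PMEPA1 (2.87) and SMAD7 (2.48), the inhibitory SMAD, were among those that rose. SMAD7 rose from 13.1 ± 2.45 to 73.1 ± 3.09 CPM. BAMBI (0.12) and TGIF2 (0.07) were not called, and the counts were the same adjusted over the list alone. The list was called higher by camera with a preset correlation of 0.01 (adjusted p = 3.21e-12), and had an adjusted p = 0.0563 with an estimated correlation.

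Ligands, receptors and SMADs of the pathway moved both ways, with 11 of 23 members higher, 6 lower and 6 uncalled (11 and 7 adjusted over the list alone). TGFBR2, the type II receptor, fell from 392 ± 46.7 to 152 ± 6.41 CPM, a log2 fold change of -1.37 (SE 0.08), while the type I receptor gene TGFBR1 rose by 0.85. The integrin gene ITGAV (1.38) and TGFB1 (0.66) rose, and ITGB8 fell (-1.60). LRRC32, which tethers latent TGF-beta, rose from 0.0911 ± 0.0560 to 0.285 ± 0.0659 CPM, but its adjusted p was 0.0759 by DESeq2 and 0.0860 without TGF-beta replicate 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list was not called by camera (adjusted p = 0.107), but was with library totals alone (0.0320) and without a filter on low counts (0.0227).

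In the list of BMP and ID genes, 9 of 12 members rose and 2 fell (9 and 1 without vehicle replicate 3), with the same counts adjusted over the list alone. The inhibitors of differentiation ID1 (1.24) and ID3 (1.51) rose with BMP2 (1.45) and the Notch target HEY1 (1.81), whereas the ligand gene BMP4 fell from 99.5 ± 24.0 to 33.0 ± 1.31 CPM, a log2 fold change of -1.60 (SE 0.21). HEY1 was scarce, at 0.265 ± 0.121 and 0.937 ± 0.0739 CPM. The camera adjusted p was 0.00423 with the preset correlation, and the adjusted p = 0.111 with an estimated correlation.

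Collagens rose in 15 of 23 tested members and fell in 4 (15 and 5 adjusted over the list alone, and 15 and 7 without vehicle replicate 1), with a median log2 fold change of 0.96. COL1A1, a chain of the main fibrillar collagen, rose from 1611 ± 85.6 to 5116 ± 360 CPM (log2 1.67, SE 0.06), and COL4A1, a basement membrane chain, from 102 ± 2.76 to 738 ± 26.1 CPM (log2 2.85, SE 0.05). COL8A2 had the largest rise, from 0.628 ± 0.0628 to 6.80 ± 0.587 CPM (log2 3.43). COL8A1 (-0.87) and COL5A3 (-1.32) fell. The list was called higher by camera (adjusted p = 0.000486), with an adjusted p = 0.112 with an estimated correlation.

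Matrix glycoproteins and proteoglycans rose in 21 of 35 members and fell in 5, the same counts as adjusted over the list alone (21 and 3 without TGF-beta replicate 1). The tenascin gene TNC (2.86), FN1 (1.95) and THBS1 (1.44), thrombospondin 1, rose. So did TNS1 (2.89), a focal adhesion gene that is not a matrix component but was in the fixed list and is counted in the 21. The basement membrane gene HSPG2, perlecan, fell from 153 ± 11.9 to 99.7 ± 4.17 CPM (log2 -0.62). Enzymes of matrix crosslinking and turnover rose in 21 of 28 members and fell in 2 (22 and 2 adjusted over the list alone). Among them, the lysyl oxidase gene LOX rose from 15.3 ± 0.476 to 86.6 ± 2.79 CPM, the transglutaminase gene TGM2 from 895 ± 143 to 1919 ± 46.7 CPM, and the metalloproteinase gene ADAM19 from 0.353 ± 0.0417 to 5.04 ± 0.588 CPM, while ADAMTS1 fell (-1.16). Both lists were called higher by camera (adjusted p = 1.71e-05 and 7.57e-08), with an adjusted p = 0.111 and 0.118 with an estimated correlation.

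Mesenchymal and contractile genes rose in 24 of 30 members and fell in 3 (25 and 3 adjusted over the list alone, and 25 and 5 without vehicle replicate 1), with a median log2 fold change of 0.73. The calponin gene CNN1 (2.52), the smooth muscle cytoskeletal gene TAGLN (2.18), the integrin gene ITGA11 (3.19) and the fibroblast protease gene FAP (3.26) led the rises. ACTA2, the smooth muscle actin often used as a myofibroblast marker, was not called, at 9.67 ± 1.60 CPM in vehicle and 8.0 ± 0.920 CPM with TGF-beta. Without vehicle replicate 1 it was called lower, at a log2 fold change of -0.39 (adjusted p = 0.000368 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). S100A4 fell from 7.06 ± 1.77 to 3.44 ± 0.361 CPM (log2 -1.04). The camera adjusted p was 1.22e-09, and the adjusted p = 0.111 with an estimated correlation.

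Transcription factors of epithelial-mesenchymal transition rose in 7 of 12 members and fell in 2, with the same counts adjusted over the list alone. The falls were 4 without vehicle replicate 1, 1 without vehicle replicate 2, vehicle replicate 3 or TGF-beta replicate 3, and 0 without TGF-beta replicate 1 or 2. SNAI1 rose from 1.81 ± 0.271 to 16.4 ± 0.918 CPM (log2 3.17, SE 0.11) and SNAI2 from 18.1 ± 0.661 to 63.1 ± 3.24 CPM (log2 1.80, SE 0.06), whereas TWIST1 fell by 0.33 and FOXC2 by 0.17, and ZEB1 was not called (-0.11), but was called lower without vehicle replicate 1 (-0.22). The camera adjusted p was 0.0108, against an adjusted p = 0.511 with an estimated correlation and 0.137 without vehicle replicate 1. TWIST1 had a log2 fold change of -0.19 without vehicle replicate 1, and its adjusted p was 0.0860, 0.0967 and 0.125 without TGF-beta replicate 1, 2 or 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That of FOXC2 was 0.164, 0.0920, 0.127 and 0.147 without vehicle replicate 2, vehicle replicate 3, TGF-beta replicate 1 or TGF-beta replicate 2.

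Epithelial junction genes were not called as a list (camera adjusted p = 0.292), with 7 of 32 members higher, 10 lower and 15 uncalled (8 and 11 adjusted over the list alone). CDH1, which encodes E-cadherin, fell from 243 ± 54.9 to 150.0 ± 5.07 CPM, a log2 fold change of -0.70 (SE 0.17) with an adjusted p of 0.0261 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That p was 0.0790 without a filter on low counts, and 0.0734, 0.0739 and 0.0724 without TGF-beta replicate 1, 2 or 3. Vehicle replicate 1 stood at 306 CPM against 219 and 204 CPM in replicates 2 and 3. With vehicle replicate 1 left out, edgeR's quasi-likelihood test gave CDH1 an adjusted p of 3.11e-11 at a log2 fold change of -0.50. The junction gene TJP3 fell from 5.40 ± 1.66 to 0.910 ± 0.0172 CPM and the claudin gene CLDN10 from 26.4 ± 3.62 to 7.41 ± 0.664 CPM, while the transcription factor gene OVOL1 rose (1.25).

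Cholangiocyte identity and transport genes were not called as a list either (camera adjusted p = 0.755, lower; higher with library totals alone, 0.856), with 6 of 25 members higher, 5 lower and 14 uncalled, also adjusted over the list alone (8 higher and 8 lower without vehicle replicate 1). KRT7 (0.95, SE 0.08) and the anion exchanger gene SLC4A2 (0.90) rose. SOX9, a transcription factor of biliary progenitors, fell from 20.9 ± 4.99 to 6.20 ± 0.259 CPM (log2 -1.76, SE 0.19), and FOXA2 fell from 32.3 ± 2.23 to 16.2 ± 0.868 CPM. KRT19 had an adjusted p of 0.603 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with a log2 value of -0.17 that was 0.09 without vehicle replicate 1.

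**Figure D4:**
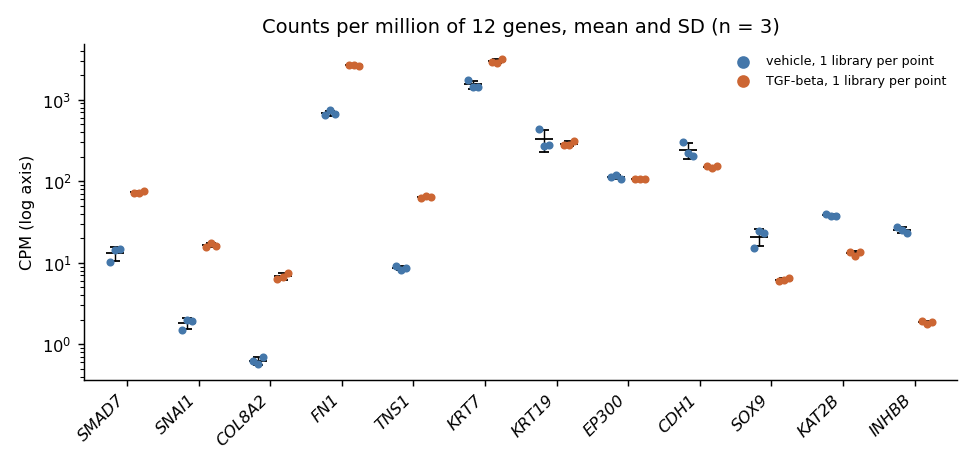
CPM on a log axis for 12 genes, with 1 point per library and black bars for the mean and SD of each condition (n = 3). SMAD7, SNAI1, COL8A2, FN1, TNS1 and KRT7 were higher with TGF-beta, CDH1, SOX9, KAT2B and INHBB were lower, and KRT19 and EP300 were not called.

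Profibrotic growth factors rose in 15 of 23 members and fell in 5 (14 and 3 without TGF-beta replicate 2 or 3), with the same counts adjusted over the list alone. ANGPTL4 rose from 6.56 ± 0.779 to 71.6 ± 3.05 CPM (log2 3.44), and PDGFB (2.06), VEGFA (1.65) and CCN2 (1.45), a matricellular growth factor, rose too. The cytokine gene IL11 rose (2.65, SE 0.55), with 3.12 CPM in vehicle replicate 1 against 14.1 and 12.8 CPM. Its adjusted p was 0.0518 and 0.0665 without vehicle replicate 2 or 3, and 0.0602, 0.0717 and 0.0667 without TGF-beta replicate 1, 2 or 3, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With vehicle replicate 1 left out, the same edgeR quasi-likelihood test gave IL11 an adjusted p of 6.94e-23 at a log2 fold change of 2.25. The EGF receptor ligands EREG (-1.91) and AREG (-1.03) fell. The camera adjusted p was 0.000554, and the adjusted p = 0.401 with an estimated correlation.

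Proliferation genes fell in 18 of 32 members and rose in 3, also adjusted over the list alone, with a median log2 fold change of -0.15. Leaving out 1 library gave 14 (without TGF-beta replicate 2) to 20 (without vehicle replicate 1) falls, and 16 or fewer without vehicle replicate 2 or 3 or TGF-beta replicate 2 or 3. MKI67, the Ki-67 antigen, fell from 478 ± 36.6 to 388 ± 10.6 CPM (log2 -0.30), the mitotic checkpoint kinase gene BUB1 fell by 0.52 and E2F2 fell by 1.07, while the cyclin gene CCNE1 rose (0.45). The list was called lower by camera (adjusted p = 0.00134), with an adjusted p = 0.111 with an estimated correlation. Cell cycle inhibitors and senescence genes were not called (camera adjusted p = 0.649), with 5 of 19 higher and 8 lower, also adjusted over the list alone. The kinase inhibitor gene CDKN1A (0.79) and the stress gene GADD45A (1.52) rose, and PLK2 (-1.14) fell. This list had a median of -0.04 and a mean of 0.08, and camera gave it a lower direction. The median was -0.10 without vehicle replicate 2, -0.06 without vehicle replicate 3, -0.07 without TGF-beta replicate 1, 0.003 without TGF-beta replicate 2 and -0.01 without TGF-beta replicate 3.

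Histone acetylation and methylation enzymes were not called as a list (camera adjusted p = 0.341), with 5 of 37 members higher and 11 lower (6 and 11 adjusted over the list alone). These were 9 and 16 without vehicle replicate 1, 3 and 9 without vehicle replicate 3, and 3 and 8 without TGF-beta replicate 2. The H3K27 demethylase gene KDM6B rose from 18.6 ± 1.65 to 68.2 ± 4.05 CPM (log2 1.88, SE 0.07), and the acetyltransferase gene KAT2B fell from 38.3 ± 1.24 to 13.2 ± 0.814 CPM (log2 -1.54, SE 0.06). EP300, another acetyltransferase gene, measured 112 ± 6.22 and 107 ± 0.323 CPM (log2 -0.07, SE 0.05) and was not called, with an adjusted p of 0.308 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was called lower with library totals alone, at a log2 fold change of -0.19, and by limma on RPKM values, at -0.13 with a pseudocount of 1.

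Genes of the unfolded protein response rose in 18 of 22 members and none fell, also adjusted over the list alone (18 and 2 without vehicle replicate 1). Changes were small, with a median log2 fold change of 0.29. CHAC1 (1.43), the transcription factor gene XBP1 (0.82) and HSPA5 (0.43), the main chaperone of the endoplasmic reticulum, rose. Glycolysis and hypoxia genes rose in 13 of 26 members and 1 fell, also adjusted over the list alone (15 and 3 without vehicle replicate 1). PFKFB3, an activator of glycolysis, rose from 25.3 ± 1.06 to 92.5 ± 1.60 CPM, LDHA rose (0.93), and the hexokinase gene HK2 fell from 13.9 ± 2.13 to 6.80 ± 0.0202 CPM. Camera called both lists higher (adjusted p = 2.80e-06 and 0.00113), and each had an adjusted p = 0.111 with an estimated correlation.

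**Figure D5:**
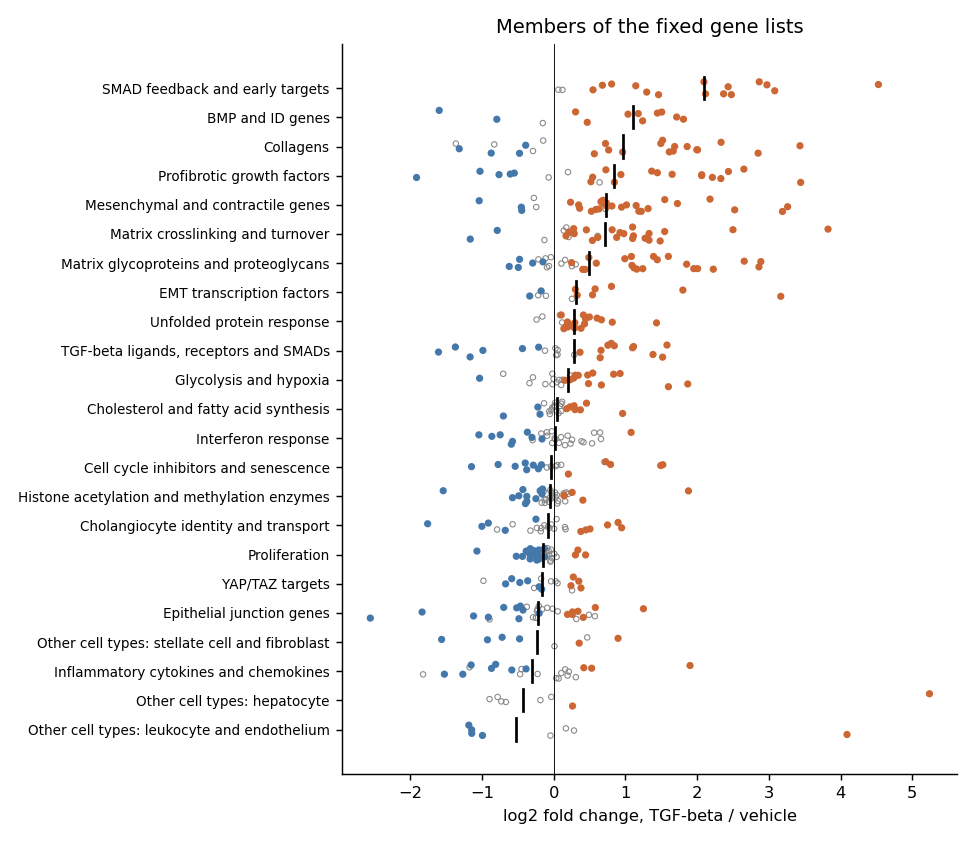
Log2 fold change (TGF-beta over vehicle) of each tested member of the 23 fixed lists, with filled points for genes called by edgeR (orange higher, blue lower), open points for uncalled genes, and a black line at each list's median. The SMAD feedback list has the highest median, 2.10.

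Inflammatory cytokines and chemokines were not called as a list (camera adjusted p = 0.221). Of 22 members, 3 were higher and 7 lower (3 and 9 adjusted over the list alone), and without vehicle replicate 1 these were 7 and 10. The chemokine genes CXCL6 (-1.52) and CXCL1 (-0.87) fell, while CCL20 rose from 0.309 ± 0.192 to 1.11 ± 0.0687 CPM. Interferon response genes were not called (camera adjusted p = 0.551), with 1 of 29 higher and 8 lower, also adjusted over the list alone. IFIT2 fell from 172 ± 21.0 to 83.3 ± 7.88 CPM, OASL fell by 0.74 and XAF1 rose (1.08). Without vehicle replicate 1, 8 interferon genes were higher and 7 lower, and without TGF-beta replicate 3, 1 and 5. The interferon median of 0.01 was 0.18, -0.03 and -0.08 without vehicle replicate 1, 2 or 3, and 0.13, -0.08 and -0.01 without TGF-beta replicate 1, 2 or 3. The list had a lower direction by camera, and a higher direction by camera without vehicle replicate 1 (adjusted p = 0.608) or TGF-beta replicate 1 (0.902).

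Targets of YAP and TAZ, the Hippo pathway coactivators, were not called (camera adjusted p = 0.477), with 4 of 17 higher and 6 lower (4 and 7 adjusted over the list alone). The tissue factor gene F3 rose (0.38) and the receptor kinase gene AXL fell from 697 ± 113 to 438 ± 11.2 CPM. Cholesterol and fatty acid synthesis genes were not called (camera adjusted p = 0.221), with 7 of 24 higher and 3 lower, also adjusted over the list alone. The lower genes were 5 without vehicle replicate 1, and 1 without vehicle replicate 2 or 3 or TGF-beta replicate 1 or 2. SCD, the stearoyl-CoA desaturase, rose from 1647 ± 82.5 to 3206 ± 32.8 CPM, and the elongase gene ELOVL6 fell (-0.70).

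Markers of other cell types were not called as lists by camera. Fry, which does not compare a list with other genes, called the hepatocyte list higher (adjusted p = 5.44e-05). It called the leukocyte and endothelium list lower (adjusted p = 0.00772 by fry) and did not call the stellate cell and fibroblast list (0.107). Hepatocyte markers (camera adjusted p = 0.580) had 2 of 8 tested members higher, HNF4A and SERPINA1 (0.26), and none lower, with a median of -0.42, a mean of 0.28 and a higher direction by camera. Without vehicle replicate 1 these were 3 higher and 2 lower with a median of -0.01, and without vehicle replicate 2 (median -0.67) or TGF-beta replicate 3 (-0.43) 1 was lower. The albumin gene ALB had 7 counts over the vehicle libraries and 1 over the TGF-beta libraries. Stellate cell and fibroblast markers (0.551) had 2 of 8 higher and 4 lower, with GLI1 rising (0.90) and TCF21 falling (-1.56). Leukocyte and endothelium markers (0.341) had 1 of 8 higher and 4 lower, with a median of -0.52, a mean of 0.01 and a lower direction by camera; PECAM1 fell (-1.18). ERG, with 5 counts in vehicle replicate 2 and 0 in the other vehicle libraries, rose from 0.0297 ± 0.0514 to 0.611 ± 0.0525 CPM; its fitted log2 fold change of 4.09 was 7.71 without vehicle replicate 2, against counts of 0, where it depends on the prior count. The list counts with all libraries were the same adjusted over each list alone.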

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

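No alternative was added after the results were seen. No gene called in the analysis of all 6 libraries was called in the opposite direction under any of them, and RLE size factors (4298 higher, 4108 lower) and DESeq2 (3822, 3475) kept both counts within 1.5 times. With library totals alone 2698 genes were higher and 7282 lower, since the TMM factors differ between conditions. A filter of at least 1 CPM in 3 samples left 484 genes at least 2-fold lower, as fewer genes were tested. On log2(RPKM + 1), 2406 genes were higher, 248 at least 2-fold higher and 72 at least 2-fold lower, and on log2(RPKM + 0.1) these were 2402, 488 and 252; these values have no TMM scaling, and the pseudocount understates changes of low genes. Leaving out 1 library gave 6259 called genes (without TGF-beta replicate 2) to 10984 (without vehicle replicate 1). With an estimated correlation camera called 0 lists higher and 0 lower (9 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 13 lists higher and 5 lower. The estimate lay under the preset 0.01 for glycolysis and hypoxia (0.00605) and for BMP and ID genes (-0.0753), and above it for the other called lists. Both of these lists also lost their calls, so a higher correlation alone does not account for the loss. The cholangiocyte list turned to the higher direction with library totals (adjusted p = 0.856), by fry (0.902) and without TGF-beta replicate 1. Leave-one-out adjusted p ranged from 0.625 to 0.993 for that list and from 0.22 to 0.902 for the interferon list, and the log2 fold change of KRT19 ranged from -0.29 to 0.0918. The cause was not tested. With the replicate number as a block 4247 genes were higher and 4330 lower, and the block changed no call of a list or named gene. Deviations from the condition means correlated by 0.07, 0.06 and 0.01 for equal numbers. Every library but TGF-beta replicate 3 correlated best with its own number in the other condition. TGF-beta replicate 3 had 0.0136 with vehicle replicate 2 against 0.0129 with vehicle replicate 3. These correlations are weak, so whether the numbers pair the samples stays open, and they were not taken to do so. Changes of 1.2-fold were mostly missed in simulation, with 13.4% recovered, but far fewer genes were changed there than were called in these data.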

Other observations

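The tests of TGF-beta RNA in vehicle replicate 1, of shared reads on chromosome 19, of gene order with merged loci and of hepatocytes, the count of genes on the same side, and the genes singled out here were chosen after the results were seen; the tests of depth, of the glucocorticoid and ERK lists and of the order of single genes were prompted by the results, but written before the values they measure were seen, and the splits were set before.

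Among non-coding genes with a mean of at least 5 CPM, called genes went both ways. RP5-1059L7.1, now named NKILA, rose from 3.87 ± 0.408 to 36.8 ± 0.0202 CPM (log2 3.25), MIR23AHG, the host of a microRNA cluster, rose (1.89), and MIAT rose from 5.45 ± 1.60 to 25.3 ± 1.68 CPM (2.20). RP5-1059L7.1 is typed as antisense. Overlaps of the non-coding genes with other genes were not checked, so their counts may hold reads of such genes. LINC00261, the largest fall in this class, went from 72.4 ± 15.5 to 10.8 ± 0.576 CPM (log2 -2.74, SE 0.19); its neighbour on chromosome 20, FOXA2, fell from 32.3 ± 2.23 to 16.2 ± 0.868 CPM, and SFTA1P (-1.71) and MIR99AHG (-1.13) fell.

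Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) called 8423 genes, and the highest of the others called 0 by edgeR's quasi-likelihood test, with at most 893 genes at an unadjusted p under 0.05 against 10130. Every other split mixes the conditions within its groups, which widens their spread, so its 0 calls do not measure the noise between libraries. With 10 splits the share cannot fall under 0.05.

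Vehicle replicate 1 differed at least 2-fold from vehicle replicates 2 and 3 in 129 genes with a mean of at least 5 CPM and a gap under 0.5 (log2) between those replicates, 84 higher and 45 lower. FKBP5, a glucocorticoid-induced chaperone gene, stood at 569 CPM against 204 and 194, and DUSP6, an ERK phosphatase gene, at 3.74 against 10.5 and 10.7. Against RNA of TGF-beta-treated cells in that library, 44.2% of the 129 genes lay away from the TGF-beta level (25) or past it by over 0.5 on the log2 scale (32), although 104 moved toward it. An admixture would also give each gene the same share of its rise. Among genes with a mean of at least 5 CPM, 29 rose by at least 3 (log2) over vehicle replicates 2 and 3. Their share in vehicle replicate 1 had a median of 1.48%, from -3.24% to 185%. These values argue against such RNA as the source of the 129 differences. After thinning of vehicle replicates 2 and 3 to the depth of vehicle replicate 1, 98.4% of the 129 genes kept a 2-fold difference. This was nearly fixed by choosing genes of at least 5 CPM with such a gap, so it cannot decide on lower depth. The chi-square per degree of freedom, which allows for library totals, was 24.1 and 26.55 for vehicle replicate 1 against vehicle replicates 2 and 3. TGF-beta replicate 1, with fewer counts (37205862 against 39971568), had 3.37 and 4.72 against TGF-beta replicates 2 and 3. These values argue against lower depth alone. Among targets not seen when the idea arose, 20 glucocorticoid receptor targets had a median log2 difference of 0.51, at percentile 100 of 10000 random lists matched on expression, and 17 ERK output genes a median of -0.65, at percentile 0 (the fixed lists also hold 1 and 4 of these genes). The percentiles measure spread over genes treated as independent, not spread between libraries, as vehicle replicate 1 is a single library. A different hormone or growth factor state may lie behind the difference, but these values cannot decide it. The TGF-beta libraries differed from vehicle replicates 2 and 3 by medians of 0.48 and -0.58 on these lists, and 98 of 121 genes chosen by the gap to vehicle replicate 2 alone lay on the same side of vehicle replicate 3 in the TGF-beta libraries, so it stays open which libraries are unusual. Of the 129 genes, 32 were called with all libraries against 120 without vehicle replicate 1. The choice of these genes favours that rise, since vehicle replicates 2 and 3 had to lie close together.

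On chromosome 19 (hg38, 49015980 to 49072941), 14 consecutive tested genes from LHB to KCNA7 rose by 3.85 to 6.07 on the log2 scale, from 764 counts in vehicle to 11982 with TGF-beta, while the flanking RUVBL2 (-0.15) and SNRNP70 (0.13) moved little. The span holds the chorionic gonadotropin beta genes, whose near-identical copies can share reads, but NTF4 and KCNA7, which are not copies of them, rose by at least 4.0. NTF4 overlaps CGB7 on the same strand, so its counts may hold CGB7 reads, while KCNA7 (4.72) overlaps no other member. None of 10000 shuffled orders held as long a run of 4-fold rises when single genes were shuffled (14 against a longest of 4), or overlapping genes were merged (8 loci against 5), each with a permutation p = 1e-04, the smallest they can give; with the copies also counted once (3 loci) the share was 0.0685, so a chance order stays open if overlapping genes and copies are not independent. Of the members 4 lie on the plus and 10 on the minus strand. Members that overlap on the same strand may share reads under any strand setting. Those on opposite strands may too, since the strand setting is not given in the sources used here. Whether the genes share a regulatory element or transcription runs across the block was not tested.

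HNF4A rose from 0.956 ± 0.0273 to 36.1 ± 1.5 CPM in a cholangiocyte line. Hepatocytes in the TGF-beta cultures are argued against, since the 7 other tested hepatocyte markers had a median log2 change of -0.665, from -0.89 to 0.26 (-0.25, from -0.45 to 0.83, without vehicle replicate 1), and the abundant liver transcripts ALB and APOA1 had 7 and 4 counts in vehicle and 1 and 4 with TGF-beta. R3HDML and RP5-881L22.5, which neighbour HNF4A and overlap each other but not HNF4A, rose as well. Whether TGF-beta acts on the locus was not tested.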
